A study of Mus musculus with 3 samples.

How the data were processed

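Stromal vascular cells of popliteal adipose tissue were measured by droplet single-cell RNA sequencing (10x Genomics version 2 chemistry, an Illumina HiSeq instrument) in 3 libraries of C57BL/6 mice, 1 per condition. The labels call the control naive, and the number of mice behind each library is not given in the sources used here. Per the labels, the tissue was freed of lymph nodes and muscle and digested with collagenase for 45 min at 37 °C, and live single cells were sorted. The dose appears in the labels without its exponent mark and was read as 1000000 colony-forming units, and the interval of 2 days is stated for the infected mice. The deposited matrices hold raw UMI counts per gene and barcode for called cells. The submitters' processing notes name Cell Ranger 2.2, Seurat 3 and the mm10 genome. The role of each tool and the annotation release are not given in the sources used here. No cell annotation was used.

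Each matrix has 27998 genes. Of these, 27722 gene IDs matched the GENCODE annotation that gave the positions, and all 271 genes named by rule were among them. A symbol carried by several genes (56 symbols) was joined to the gene ID. Cells needed at least 200 genes and at most 10% mitochondrial UMIs, which left out 3, 2 and 1 and then 22, 6 and 8 barcodes. Values in groups of 3 follow the order control, PBS, infected. Doublets were taken as the highest Scrublet scores of a library, 0.8% per 1000 barcodes, which removed 553, 301 and 860 cells, whereas Scrublet's automatic threshold called 3.13, 1.94 and 0.868% of cells. In all, 23082 cells were used, with medians of 1638, 1467 and 1449 genes and 2.48, 2.14 and 1.83% mitochondrial UMIs.

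All cells were clustered together without batch correction, since library and condition are the same factor. The 2000 most variable genes were chosen per library and combined, without mitochondrial, ribosomal and sex-linked genes and without members of the interferon, MHC, cytokine, NF-kB, acute phase, antimicrobial, cell cycle and stress lists. Then 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 27 clusters. A cluster took the class of the best of 23 marker sets if the score was at least 1, at least 3 markers were detected at 20 CPM, and the next set was 0.25 behind or a leading gene was a marker of the class. It stayed unnamed if its 10 leading genes held more markers of another type, or if a mural score came with keratins among the 20 leading genes. These naming thresholds were set after the data were seen. They named 21 clusters in 9 classes and left 6 unnamed.

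Counts were summed over the cells of a class in a library and divided by the class total to give CPM. Classes with at least 100 cells in every library were compared gene by gene, which gave fibroblast-like, macrophage-like, epithelial-like and T-like cells. A gene counted as measured with at least 30 UMIs over the libraries and at least 20 CPM in 1 of them (5597, 5722, 5591 and 4332 genes). Log2 folds used a pseudocount of 5 CPM. Ratios have no pseudocount. Intervals are exact at 95%: Poisson for CPM, Clopper-Pearson for shares and conditional binomial for ratios. A gene at 0 in the lower library was given the ratio against a floor of 3 counts in that class and library. Cells are not replicates, so no p-value was computed. A gene was called higher or lower in infected cells at 2-fold against both other libraries. Free RNA was estimated as the level of markers of other classes, which was 5.40%, 5.34%, 3.31% and 3.95% of their level over the whole library in the 4 classes of the infected library.

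The comparisons, the gene lists, the main settings and the other settings listed last here were chosen before the data were examined. There were 20 lists: interferon-gamma response, type I interferon response, MHC class I and class II presentation, cytokines and chemokines, NF-kB targets and adhesion, acute phase and complement, antimicrobial effectors, extracellular matrix, adipogenesis and lipid handling, glycolysis, oxidative phosphorylation, cell cycle, dissociation stress, lymphocyte effector, resident macrophage, inflammatory monocyte, Pi16 Dpp4 progenitor, committed preadipocyte and F3 regulatory stromal. A list was summarised by the median log2 fold of its measured members and its percentile among 10000 random lists matched on mean expression in 20 bins. Genes were named by rule. In the 3 largest classes these were the 12 genes higher and the 6 lower with the largest smaller-of-both fold in infected cells, and in T-like cells 4 and 2. For PBS against control they were up to 6 each way in the 3 largest classes. The rule left out ribosomal, mitochondrial, hemoglobin and receptor segment genes, Xist and Y-linked genes, markers of other classes, unnamed predicted genes, and genes under 10% of their highest class. List members with extreme folds and 8 cytokine genes were added, and other genes named as cluster leaders or cell sources were chosen after their values were seen. Some genes that the rule named are not reported here.

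The fold, interval and list steps were tested on simulated data: counts drawn at the depth of the infected and PBS class sums, with 200 genes set to differ before filtering. The draws held counting error only, with no difference between animals or libraries. Clustering, naming and doublet removal were not simulated. Genes set at 4-fold came back at median log2 folds of 1.92, 1.89, 1.85 and 1.91 in fibroblast-like, macrophage-like, epithelial-like and T-like cells. Intervals held the true ratio for 95.6, 95.6, 95.1 and 95.8% of genes. Genes set equal passed the fold of 2 in 0, 0, 0 and 1.55% of cases, which does not tell how often libraries of the same condition would pass it. A list of changed genes reached percentile 100 and a list of unchanged genes 29.9, 62.7, 69.0 and 19.2.

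The other settings were at least 500 genes per cell, at most 5% mitochondrial UMIs, no doublet removal, Scrublet's automatic threshold, Leiden resolutions 0.5 and 2.0, response lists kept among variable genes, shares without T-like and B-like cells, TMM factors (edgeR 4.0.16), cells thinned to 1000 UMIs, the mean of per-cell CPM, pseudocounts of 1 and 20 CPM, and low-count filters of 5 and 100 UMIs. Before the pseudocount, TMM factors moved log2 CPM ratios of infected over PBS by 0.16, 0.23, 0.02 and 0.18 in the same 4 classes. Software was Python 3.11.15, scanpy 1.11.5 (with Scrublet), numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, with seed 0.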

Results

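The stromal vascular fraction of popliteal fat, which is what remains of the tissue once fat cells are taken away, was profiled by droplet single-cell RNA sequencing in C57BL/6 mice. There were 3 libraries, 1 of naive control mice, 1 of mice given phosphate-buffered saline (PBS) in the footpad and 1 of mice given 1000000 colony-forming units of the bacterium Listeria monocytogenes in the footpad and sampled on day 2. Live single cells were sorted before loading. Values given in groups of 3 follow the order control, PBS, infected. The libraries held 8327, 6136 and 10375 barcodes and 43592672, 29452423 and 54031704 unique molecular identifiers (UMIs). Of these barcodes, 7749, 5827 and 9506 cells were used, with medians of 4625, 4091 and 4284 UMIs per cell. No condition had a replicate, so no difference between libraries carries a test, and every interval, printed in parentheses at the 95% level, covers counting error only. Levels are in CPM, UMI counts scaled to a common total of 1e6 UMIs, over all cells of a class in a library. Cell classes carry the ending -like because they rest on marker genes.

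Gene positions are given on the mm10 build: Saa3 (ENSMUSG00000040026) at 46711998 to 46715700 of chromosome 7, Cxcl9 (ENSMUSG00000029417) at 92321347 to 92328079 of chromosome 5, Cxcl10 (ENSMUSG00000034855) at 92346638 to 92348889 of chromosome 5 and Gbp2 (ENSMUSG00000028270) at 142620602 to 142638008 of chromosome 3. The lymphocyte genes lay as follows: Ifng (ENSMUSG00000055170) at 118441046 to 118445892 of chromosome 10, Il22 (ENSMUSG00000074695) at 118204942 to 118210047 of chromosome 10, Il17a (ENSMUSG00000025929) at 20730905 to 20734496 of chromosome 1 and Il5 (ENSMUSG00000036117) at 53720794 to 53725106 of chromosome 11. The epithelial gene was Gpx3 (ENSMUSG00000018339) at 54902453 to 54910377 of chromosome 11. All are protein-coding genes.

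Comparing the infected library with both others asked which cells this fat held 2 days after bacteria reached the footpad, and what those cells expressed. Monocyte-like cells made up most of the infected library and were rare in the others. Fibroblast-like cells, the leading class of the control and PBS libraries, were a minority of the infected one. All 4 classes compared gene by gene, which were fibroblast-like, macrophage-like, epithelial-like and T-like cells, carried an interferon program in the infected library. In the infected library Ifng was concentrated in NK-like cells, Saa3 and Cxcl9 in fibroblast-like cells, and Il22 and Il17a were found in T-like cells of the infected library.

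Monocyte-like cells were 0.723% of control cells, 2.97% of PBS cells and 61.6% (60.6 to 62.5) of infected cells, an infected to PBS ratio of 20.7 (17.8 to 24.3). Most of them lay in clusters 20, 21 and 26, which held 2563, 1997 and 1210 infected cells, against 0, 3 and 14 PBS cells and 0 control cells in each. Cluster 18 was the shared monocyte-like cluster, with 56, 156 and 82 cells. Neutrophil-like cells numbered 1, 6 and 97, and their infected to PBS ratio of shares was 9.91 (4.39 to 27.7). Neutrophils hold little RNA, and the shallowest cells used had 1829, 1602 and 1871 UMIs. Fibroblast-like cells were 50.4%, 40.5% and 14.8% of cells, an infected to PBS ratio of 0.366 (0.342 to 0.391). Epithelial-like cells were 16.0%, 13.2% and 3.69%, a ratio of 0.281 (0.247 to 0.319). Macrophage-like cells were 10.7%, 8.89% and 4.42%, a ratio of 0.497 (0.436 to 0.566). These shares are of all cells, so the many infected monocyte-like cells lower the shares of all other classes by construction. Macrophage-like cells numbered 827, 518 and 420, and their share without monocyte-like cells was not computed. Their ratio therefore does not show that they became fewer. T-like cells were 1.63%, 3.09% and 2.72%. NK-like cells were 1.29%, 2.08% and 0.989%, an infected to PBS ratio of 0.476 (0.360 to 0.629), which turned to 2.34 without the clusters over 90% infected. B-like cells were 0.232%, 0.412% and 0.684%, and the class also held RNA of the myeloid gene Lyz2, at 5093, 807 and 6448 CPM. Skeletal muscle-like cells were 0.594%, 1.61% and 0.200%.

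Among non-immune cells alone, which takes the monocytes out of the denominator, fibroblast-like cells were 62.8%, 53.7% and 66.6% and epithelial-like cells 19.9%, 17.5% and 16.6%. Among these 2 classes alone, the infected to PBS ratio of fibroblast-like cells turned to 1.06. The naming rules left 6 clusters unnamed, and together they held 18.4%, 27.2% and 9.90% of cells. For some of them the marker scores did favour 1 class. Cluster 6 scored 3.96 for fibroblasts against 1.36 for the next set, and cluster 12 scored 2.67 for epithelium against 0.93. Both stayed unnamed because 1 of their 10 leading genes was a marker of another type and none was a marker of the best class. Cluster 6, with fibroblast genes and a low UMI count, held 10.2%, 10.2% and 0.663%, and cluster 9, led by Retnla, Ear2 and Cd209a, held 5.05%, 6.62% and 0.694%. Cluster 12, led by Upk3a, Fgb and Areg with epithelial keratins, held 2.06%, 9.03% and 2.51%, and cluster 22, led by Ifitm1, Cd7 and Sct, held 0.168%, 0.429% and 5.66%. Clusters 15 and 24 held 0.774%, 0.807% and 0.358%, and 0.142%, 0.103% and 0.0105%. No cluster was named endothelial, and Cdh5, a gene of endothelial junctions, stood at 0.504, 0.219 and 0.947 CPM over all cells.

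**Figure D1:**
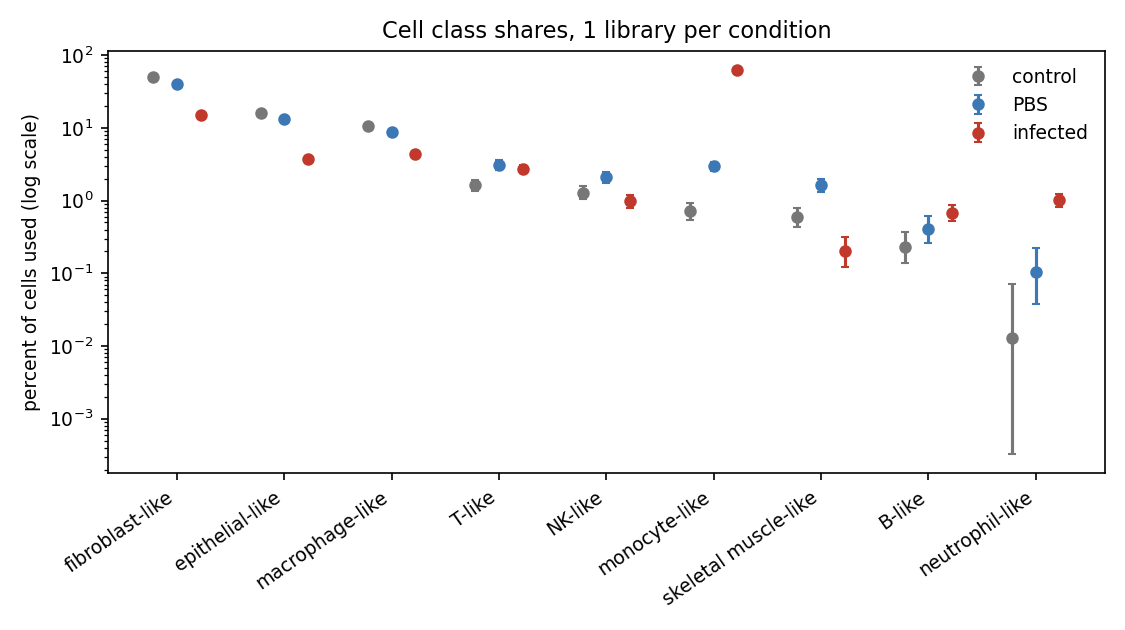
Percent of the cells used (log scale) for the 9 named classes in the control, PBS and infected libraries, with bars for the 95% interval of counting error. Monocyte-like cells sit at 0.723% in control and 61.6% in infected, and fibroblast-like cells at 50.4% and 14.8%.

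Fibroblast-like cells of the infected library expressed acute-phase, chemokine and interferon genes at levels far above both other libraries. Saa3, a serum amyloid A protein of the acute phase, stood at 1.82, 2.50 and 7424 CPM, 2975-fold (2030.4 to 4555) higher in infected than in PBS. Cxcl9, a chemokine that draws activated T and NK cells, stood at 139.8, 109.7 and 3747 CPM, 34.2-fold (32.2 to 36.3) higher. Cxcl5, a neutrophil-attracting chemokine, stood at 1.06, 0.192 and 318 CPM, 1659-fold (459 to 13706) higher over 2 PBS UMIs. The guanylate-binding protein gene Gbp4 stood at 1.82, 2.50 and 247 CPM, and the siderophore-binding Lcn2 at 8.16, 5.66 and 425 CPM. Rsad2 and Mx1, antiviral genes of the interferon response, were 24.5-fold (22.05 to 27.4) and 60.5-fold (41.4 to 92.1) higher than in PBS. The serpin Serpina3g was 58.2-fold (38.9 to 91.2) higher, Fam26f 60.8-fold (47.3 to 79.4), and the pore-forming Mpeg1 72.6-fold (45.1 to 125). AA467197 was 39.3-fold (28.4 to 56.1) higher, and it and Fam26f also led monocyte-like clusters. The protease inhibitor gene Timp1, which also led cluster 23, was 25.7-fold (23.1 to 28.8) higher. Lcn2, Rsad2, Mpeg1 and AA467197 were at 14.3%, 16.1%, 18.2% and 11.4% of their highest class. Members of the fixed lists higher in infected cells included Isg15 (135, 155 and 2319.8 CPM), the peptide transporter gene Tap1 (26.4, 30.8 and 271 CPM), the immunoproteasome gene Psmb9 (26.7, 36.2 and 269 CPM) and the immune checkpoint ligand Cd274 (11.4, 12.7 and 238 CPM). Lists of NF-kB and complement genes held Sod2 at 121, 117 and 1110.2 CPM and Ptx3 at 819.6, 795 and 4264 CPM, and the complement gene Cfb 9.59-fold (8.15 to 11.3) higher than in PBS. Ccl2 stood at 645, 569.8 and 4729.5 CPM and Cxcl10 at 693, 531 and 5726 CPM. Il6 stood at 369.7, 327 and 783 CPM and Cxcl1 at 1685, 1967 and 3909 CPM, while Irf1 differed little, at 571, 535 and 640.0 CPM.

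Genes lower in infected fibroblast-like cells included genes named by rule, given first and not members of the progenitor list, and then members of that list. The sphingomyelinase gene Smpd3 stood at 239, 170.0 and 35.4 CPM, the ligand Wnt5a at 83.8, 82.0 and 22.8 CPM, the Wnt antagonist Dkk2 at 152, 139.6 and 45.3 CPM and Gas1 at 212, 163 and 53.4 CPM. Fam198b and Stmn4 stood at 50.8, 48.6 and 13.2 CPM, and 44.7, 50.6 and 12.2 CPM. Of the Pi16 Dpp4 progenitor list, 7 of 10 measured members were lower in infected than in both others, with a median log2 fold over PBS of -1.16. Among them were Sema3c at 404, 442 and 161 CPM and Efhd1 at 172, 155 and 59.6 CPM, whereas Pi16 stood at 2076, 2499 and 1588 CPM. The F3 regulatory stromal list had 2 of 4 members lower and a median of -0.83, with Gdf10 at 33.9, 41.8 and 9.45 CPM, Igfbp3 at 195, 209 and 92.0 CPM and F3 at 61.5, 52.1 and 57.2 CPM. The committed preadipocyte list had a median of 0.07 over PBS and -0.49 over control, the first being -0.02 with cells thinned to 1000 UMIs, and its member Cxcl14 stood at 126, 136 and 498 CPM. The extracellular matrix list had a median of -0.50, with 2 of 28 members lower. Eln stood at 334, 257 and 147 CPM and Col15a1 at 248, 150.4 and 75.1 CPM. With the pseudocount both were under 2-fold against PBS, so neither counts among the 2. Several of these genes also led shared clusters: Smpd3, Sema3c and Efhd1 cluster 5, Dkk2 cluster 3, Igfbp3 cluster 11, Gdf10 and Eln cluster 2, and Col15a1 and Lpl cluster 1. The adipogenesis list had a median of -0.06 over PBS, or 0.09 with TMM factors, and -0.48 over control. Its member Lpl stood at 1147, 899 and 448 CPM and the carbonic anhydrase gene Car3 at 58.8, 37.2 and 12.2 CPM. The stress list had a median of -0.47, with Atf3 at 1221, 1201 and 658 CPM.

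The fibroblast-like cells of the libraries lay in different clusters. Cluster 23 held 845 of 1408 infected fibroblast-like cells, or 60.01%, and 0 cells of control or PBS. Clusters 1 and 5 held 36.2% and 35.6% of control fibroblast-like cells, 21.97% and 41.7% of PBS ones, and 7.60% and 12.6% of infected ones. Saa3 stood at 10895 CPM in cluster 23 and at 108 CPM in the infected cells of the clusters shared with the other libraries. Cxcl9 in those shared clusters stood at 605 CPM. Without cluster 23, the interferon-gamma list median over PBS was 1.49 in place of 2.76, the extracellular matrix and F3 regulatory stromal medians turned to 0.11 and 0.19, and Igfbp3 over PBS and Eln over PBS and over control turned to 0.03, 0.54 and 0.16 on the log2 scale. In 1 random thinning to 1000 UMIs, 53.8% (50.4 to 57.2) of cluster 23 cells and 7.82% (5.74 to 10.3) of the shared-cluster cells had a Saa3 UMI, against 8.83% of infected epithelial-like cells, taken as the background. The means over all possible draws were 55.5%, 9.08% and 9.20%, so the shared-cluster share was near the background. Unthinned, the shares were 76.0%, 36.2% and 49.3%, at median depths of 7287, 5302 and 7090 UMIs.

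**Figure D2:**
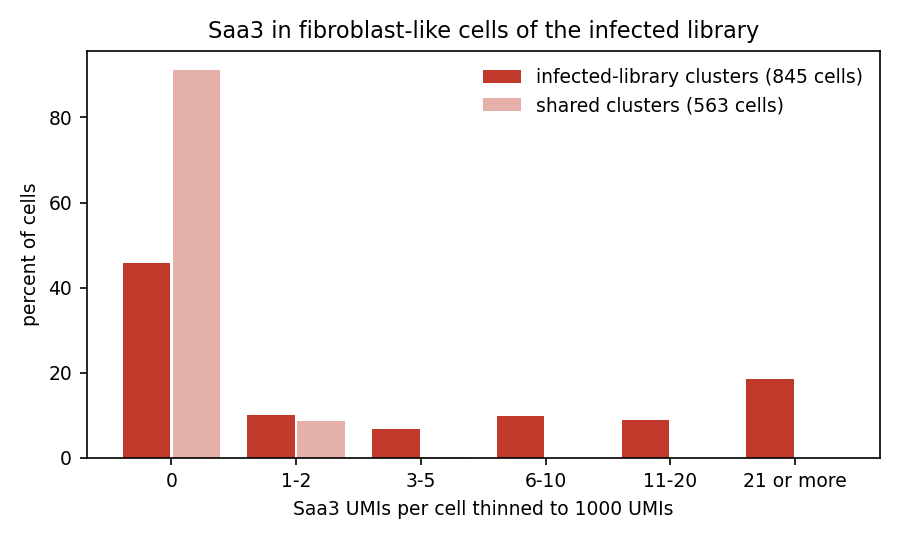
Percent of infected fibroblast-like cells (bars) by the number of Saa3 UMIs per cell after each cell was thinned to 1000 UMIs, for 845 cells of cluster 23 and 563 cells of the clusters shared with the other libraries. Of these cells, 54.2% and 8.88% had at least 1 Saa3 UMI in the random draw shown.

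Macrophage-like cells of the infected library carried interferon and monocyte genes and less of the genes of resident macrophages. Cxcl10 stood at 109, 112 and 3811 CPM, 34.1-fold (29.6 to 39.4) higher in infected than in PBS, and Ccl5 at 61.3, 49.4 and 1820.1 CPM, 36.9-fold (29.8 to 46.1) higher. Irg1, now named Acod1, whose product makes itaconate, stood at 0.358, 5.68 and 409 CPM. Slfn4 was 50.3-fold (31.3 to 86.6) higher, the exonuclease gene Isg20 25.6-fold (18.2 to 37.1), the inhibitory receptor gene Cd300lf 61.9-fold (24.0 to 228) and AW112010 18.1-fold (15.8 to 20.95). Ifit1bl1 had 0 PBS UMIs and was at least 106-fold higher, against a floor of 3 counts in the class. AA467197, with 1 PBS UMI, was 1112-fold (199 to 43948) higher, Upp1 with 2 UMIs 100.3-fold (27.5 to 832) and Ly6i 43.5-fold (23.5 to 91.1), and these 3 genes also led the monocyte-like cluster 20. Fixed lists added Isg15 at 114, 297 and 3916 CPM, Rsad2 at 90.7, 149.9 and 2049 CPM, Gbp4 at 6.45, 14.2 and 321 CPM, Gbp5 at 7.17, 17.6 and 309.8 CPM and Tap1 at 52.3, 94.8 and 465 CPM. Irf1 stood at 186, 416 and 614 CPM. The glycolysis list had 6 of 15 members higher, with Pfkp at 21.9, 22.7 and 133 CPM and Hif1a at 75.6, 80.0 and 374 CPM. Of the inflammatory monocyte list, 10 of 12 members were higher, with a median log2 fold of 3.38. Ly6c2 stood at 15.1, 30.7 and 1928 CPM, or 27.6% of its highest class, and Plac8 at 79.6, 296 and 5988 CPM. Lyz2, abundant in monocytes, was not higher, at 7383, 6828 and 6322 CPM.

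Of the resident macrophage list, 11 of 13 measured members were lower in infected macrophage-like cells than in both others, with a median log2 fold over PBS of -1.54. The mannose receptor gene Mrc1 stood at 1166, 1095 and 473 CPM, Retnla at 14499, 15164 and 5709 CPM, the lectin gene Cd209f at 1702, 1632 and 366 CPM and the chemokine Ccl24 at 1058, 1071 and 233 CPM. Rasgrp3 stood at 81.7, 63.6 and 7.12 CPM, thrombomodulin (Thbd) at 28.0, 27.8 and 1.499 CPM, the clock gene Nr1d1 at 44.4, 29.5 and 2.25 CPM and Cmah at 145, 115 and 22.9 CPM. The fatty acid receptor gene Cd36 stood at 917, 800.5 and 182 CPM and Fosb at 1534, 1135 and 482 CPM. Cluster 19 held 341 of 420 infected macrophage-like cells, while cluster 10 held 99.6% of control and 98.6% of PBS ones. The median cell held 6022 UMIs in cluster 19 and 3062.5 in cluster 10. Cluster 19 also had the highest median Scrublet doublet score of the 27 clusters, 0.119 against 0.0177 in cluster 10, and monocyte markers as its next best set, so doublets with monocytes were not excluded there. Without cluster 19, the interferon-gamma list median was 1.33, the resident list median turned to 0.11, and Mrc1 and Hif1a turned to 0.15 and -0.13.

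Epithelial-like cells of the infected library had the highest interferon-gamma list median of the 4 classes. Their cluster 7 was led by Slc12a2, Prlr and Wfdc2, and cluster 8 by Wfdc18, the casein gene Csn3 and Plet1. The labels do not give the tissue these cells came from, and whether they belong to the fat itself was not settled. Cxcl10 stood at 22.5, 19.9 and 1928 CPM, 97.0-fold (79.7 to 119) higher in infected than in PBS. Cxcl9 stood at 3.14, 3.74 and 608 CPM, 163-fold (104 to 271) higher. Gbp2 stood at 12.4, 26.0 and 1851 CPM, 71.3-fold (59.95 to 85.4) higher, and Gbp7 was 57.9-fold (40.0 to 87.0) higher. Gbp4, with 2 PBS UMIs, was 217-fold (59.5 to 1807) higher. The immunity-related GTPase genes Irgm1, Igtp and Ifi47 were 62.1-fold (42.4 to 94.7), 53.7-fold (36.1 to 83.6) and 62.3-fold (36.7 to 115) higher. Ifit3 was 80.1-fold (45.4 to 156) higher and Cxcl5 67.9-fold (42.0 to 117). The ubiquitin-like gene Ubd stood at 10.5, 28.7 and 558 CPM. Nos2, which makes nitric oxide, had 0 UMIs in control and PBS and 38.0 CPM in infected, at least 64.4-fold higher than PBS. Ido1 stood at 79.6, 30.5 and 488 CPM, Tap1 at 15.6, 16.7 and 193 CPM, Lcn2 at 505, 588 and 2976 CPM and the triglyceride enzyme gene Dgat2 at 82.5, 82.3 and 616 CPM. On the lower side, the glutathione peroxidase gene Gpx3 stood at 1540.3, 318 and 102 CPM, the defensin gene Defb1 at 61.2, 29.5 and 6.47 CPM, the iodide transporter gene Slc5a5 at 104, 92.9 and 26.6 CPM and Fxyd2 at 247, 119 and 32.0 CPM. Aoc1 stood at 23.6, 32.1 and 4.18 CPM, and Ly6k at 12.8, 27.2 and 0.3804 CPM, the last from 1 UMI.

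T-like cells of the infected library held UMIs of the cytokine genes Il22, Il17a and Il17f, which had few or none in the others. Il22 had 0 UMIs in control and PBS and 1467 CPM in infected, at least 209.7-fold higher than PBS. Il17a also had 0 UMIs in both and 617 CPM in infected, at least 88.2-fold higher, and Il17f stood at 2.77, 0 and 349 CPM, at least 49.95-fold higher. The type 2 cytokine genes Il5 and Il13 went the other way: Il5 stood at 105, 139.9 and 6.40 CPM and Il13 at 99.7, 18.7 and 2.56 CPM. Csf2 stood at 30.5, 51.3 and 6.40 CPM, Arg1 at 103, 56.0 and 3.84 CPM, Ccdc184 at 49.9, 49.0 and 2.56 CPM and the mitotic gene Birc5 at 83.1, 39.6 and 17.9 CPM. Gbp2 stood at 49.9, 53.6 and 395 CPM, Tapbp at 108, 126 and 366 CPM, Ifit3 at 5.54, 4.66 and 259.8 CPM and Mx1 at 0, 0 and 87.0 CPM. Gzmb stood at 27.7, 166 and 817 CPM, its infected value was 14.4% of the highest class, and it also led the NK-like cluster. Ifng stood at 44.3, 93.3 and 34.6 CPM, and its direction against PBS turned under 5 other settings. The class held 126, 180 and 259 cells. It was named by T cell markers, and whether all of its cells are T cells was not determined. A different mix of cells and a different level per cell are not separated by the class values. At clustering resolution 2.0 the class held 97, 149 and 234 cells. There the log2 folds over PBS of Il5, Il13, Csf2 and Ccdc184 were 0, and that of Il17a was 3.86 in place of 6.96. The difference in the first 4 genes thus rested on cells that this setting placed outside the class. The lymphocyte effector list had 3 of 11 members higher and 2 lower.

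Gene lists fixed beforehand describe the same contrast over whole programs. List values follow the order fibroblast-like, macrophage-like, epithelial-like, T-like. Of the interferon-gamma response list, 19 of 21, 21 of 23, 19 of 19 and 18 of 19 measured members were at least 2-fold higher in infected cells than in both others. Median log2 folds over PBS were 2.76, 2.40, 4.03 and 1.69, each at percentile 100 among 10000 random lists of matched expression. Of the type I interferon list, 24 of 25, 23 of 25, 25 of 25 and 23 of 23 members were higher, with medians of 2.58, 2.42, 3.28 and 2.83. The MHC class I list had 13 of 15, 10 of 15, 14 of 15 and 4 of 15 members higher and medians of 1.89, 1.54, 1.75 and 0.76. The MHC class II list had 5 of 7, 1 of 8, 3 of 7 and 1 of 7 members higher and medians of 1.29, 0.31, 1.18 and -0.37 over PBS and 1.42, -0.05, 1.15 and 0.47 over control, the T-like one over PBS turning to 0.39 with thinned cells. The cytokine and chemokine list had 18 of 22, 10 of 21, 12 of 16 and 6 of 11 members higher and medians of 2.18, 1.22, 2.00 and 1.33. The NF-kB and adhesion list had 4 of 13, 3 of 14, 2 of 12 and 1 of 12 members higher, with lower medians of 0.53, 0.39, 0.67 and 0.30, the T-like one turning to -0.21 with thinned cells. The antimicrobial list had 7 of 7, 6 of 11, 7 of 8 and 4 of 4 members higher and medians of 3.51, 1.05, 2.47 and 2.19. It holds genes abundant in monocytes, and RNA of other cells was not excluded for it. Its member Lyz2 stood at 243 and 270 CPM in infected epithelial-like and T-like cells, against 10999 CPM in monocyte-like cells. Random lists matched to it were also above 0 in fibroblast-like and T-like cells, at medians of 0.63 and 0.42. The acute phase and complement list had 7 of 13, 5 of 9 and 3 of 7 members higher outside T-like cells, with medians of 1.10, 1.05 and 1.73, and too few members measured in T-like cells.

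Glycolysis had medians of 0.34, 0.71, 0.11 and 0.16 and oxidative phosphorylation 0.04, 0.14, -0.05 and 0.10. The adipogenesis list had medians of -0.76, -0.08 and -0.27 in macrophage-like, epithelial-like and T-like cells, the epithelial-like one turning to 0.07 with thinned cells. The cell cycle list had medians of -0.37, -0.89 and -0.83 in the same 3 classes over PBS, and -0.41, 0.36 and -1.19 over control. The stress list had medians of -0.47, -0.74, -0.03 and -0.66 over PBS and -0.60, -0.58, 0.26 and -0.71 over control. Fibroblast, matrix and monocyte genes in other classes include RNA from other cells: the level of fibroblast genes in infected epithelial-like cells was 3.31% of their level over the library, so the matrix and fibroblast lists are described for fibroblast-like cells. The inflammatory monocyte list is given for macrophage-like cells, where RNA of monocyte-like cells was not excluded. Gbp2 and Gbp2b, Ifit3 and Ifit3b, Ifit1bl1 and its relatives, and Hspa1a and Hspa1b are close copies whose UMIs may be assigned to the wrong copy.

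**Figure D3:**
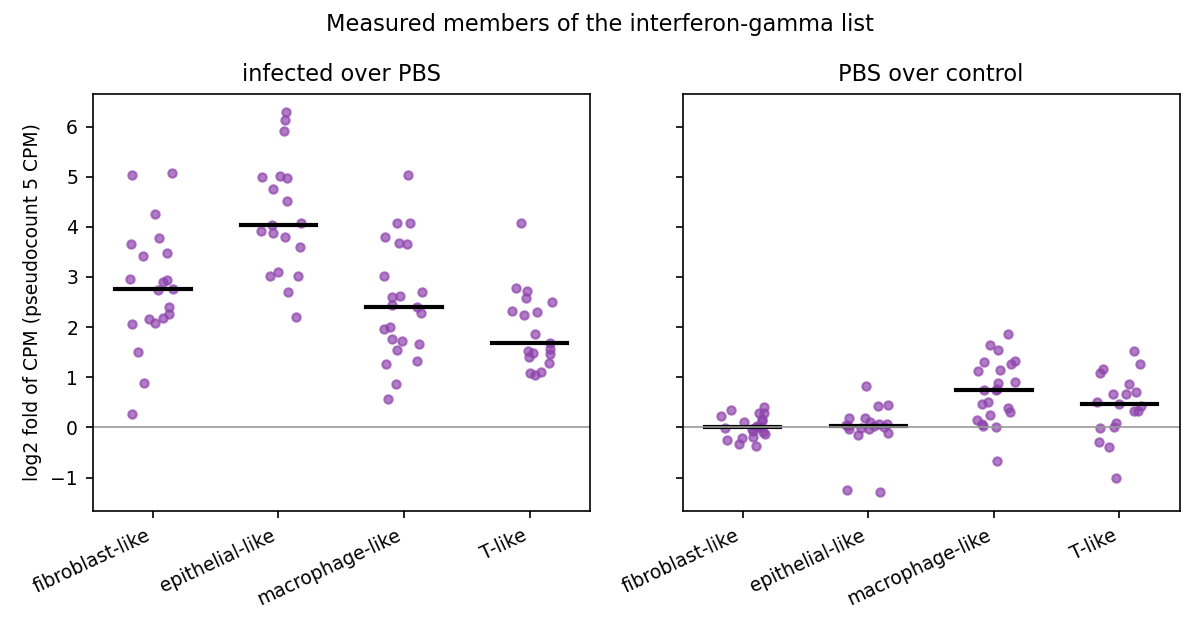
Log2 fold of CPM (pseudocount 5 CPM) of each measured member of the interferon-gamma response list in 4 cell classes, infected over PBS in one panel and PBS over control in the other. Each point is a gene and each line the median, which is 4.03 in epithelial-like cells for infected over PBS and 0.75 in macrophage-like cells for PBS over control.

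The cytokine genes had different main sources. NK-like cells held 42%, 40.2% and 89.3% of the Ifng UMIs of the libraries, and Ifng stood at 76.1, 128 and 5376 CPM in them. T-like cells held 32%, 43.5% and 1.57%, so the main source stood apart only in the infected library. Ifng also led the NK-like cluster and was not among the genes kept out of the clustering, so the split between these classes may depend on it. Monocyte-like cells held 81.8% of Tnf UMIs and 77.4% of Il1b UMIs of the infected library. In control, macrophage-like cells held 63.7% of Tnf and cluster 9 held 58.1% of Il1b. Fibroblast-like cells held 60.7% of Il6, 88.4% of Cxcl1 and 54.2% of Cxcl9 in the infected library, while making up 14.8% of its cells. Monocyte-like cells held 33.9% of Il6 and 34.6% of Cxcl9. Ccl2 was split between monocyte-like cells, 53.6%, and fibroblast-like cells, 39.2%. Monocyte-like cells held 65.5% of Cxcl10 and fibroblast-like cells 20.2%. Since monocyte-like cells were 61.6% of the infected cells, their shares of Ccl2 and Cxcl10 largely follow their number.

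**Figure D4:**
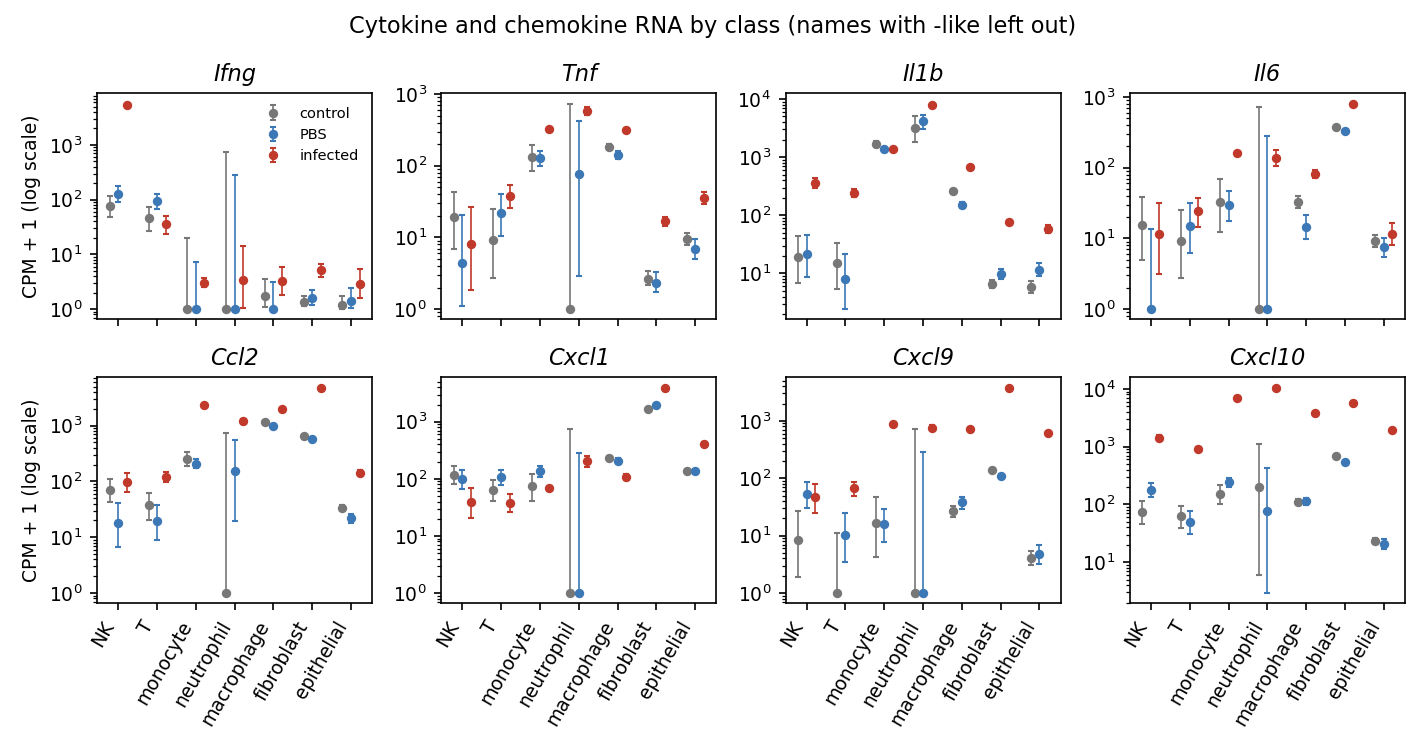
CPM + 1 (log scale) of 8 cytokine and chemokine genes in 7 cell classes of the control, PBS and infected libraries, 1 panel per gene, with bars for the 95% interval of counting error. Ifng reaches 5376 CPM in infected NK-like cells, and Cxcl9 reaches 3747 CPM in infected fibroblast-like cells.

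Infection and library are the same factor here, and over 90% of the cells of clusters 19 to 23, 25 and 26 were infected ones. The monocyte-like ratio was 1.58 without such clusters and 111 at the coarser clustering, the epithelial-like ratio turned to 1.38 without them, and the list medians ranged from 3.07 to 5.22 in epithelial-like cells with pseudocounts of 20 and 1 CPM.

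Comparing PBS with control asked what a footpad injection without bacteria left in this fat. The composition differed far less than in the infected library. Macrophage-like and T-like cells of the PBS library had part of the interferon program, fibroblast-like and epithelial-like cells had interferon-gamma list medians near 0, and the cell cycle list was higher in epithelial-like cells.

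Fibroblast-like cells had a PBS to control ratio of shares of 0.803 (0.762 to 0.845), epithelial-like cells 0.823 (0.751 to 0.901) and macrophage-like cells 0.833 (0.745 to 0.931). Monocyte-like cells were 4.11 (3.02 to 5.66) times as frequent, T-like cells 1.90 (1.505 to 2.40), NK-like cells 1.61 (1.22 to 2.12) and skeletal muscle-like cells 2.72 (1.89 to 3.96). The ratio for cluster 12 was 4.37 (3.66 to 5.25). The direction of the epithelial-like ratio is not settled. It turned to 1.23 with at least 500 genes per cell, 1.23 at clustering resolution 0.5 and 1.01 at 2.0, 1.24 without doublet removal, 1.24 with Scrublet's own doublet threshold, 1.23 with clusters named without their leading genes, and 1.02 among fibroblast-like and epithelial-like cells alone. In the 3 settings at 1.23 the class held 1400, 1293 and 590 cells, in place of 1240, 767 and 351. These counts match the main class with cluster 12, of 160, 526 and 239 cells, added. The direction there thus depended on whether cluster 12 was counted as epithelial-like.

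In fibroblast-like cells, the transcription factor gene Zbtb16 stood at 21.5 CPM in control and 82.5 in PBS, 3.84-fold (3.42 to 4.32) higher, and it was the one named gene on the higher side. On the lower side, the isoprenoid enzyme gene Idi1 had a PBS to control ratio of 0.364 (0.302 to 0.436). The ratio was 0.403 (0.365 to 0.445) for the aggrecanase gene Adamts4, 0.348 (0.279 to 0.431) for Ngfr, 0.420 (0.372 to 0.473) for Col18a1 and 0.348 (0.287 to 0.419) for AY036118. The interferon-gamma list median was 0.00 and the extracellular matrix median -0.11. The committed preadipocyte list had a median of -0.35, below all 10000 random lists, and fewer PBS fibroblast-like cells lay in cluster 1, which the list's genes Fabp4, Col15a1 and Lpl led.

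In macrophage-like cells, 8 of 23 interferon-gamma list members were at least 2-fold higher in PBS than in control, with a median log2 fold of 0.75, and 6 of 25 type I interferon members were, with a median of 0.75. The GTPase genes Iigp1 and Igtp were 3.88-fold (3.22 to 4.69) and 3.64-fold (2.67 to 4.995) higher, and Irf1 was 2.23-fold (1.99 to 2.50) higher. The chemokine Ccl12, which also led cluster 19, was 3.97-fold (3.64 to 4.32) higher, and the adhesion receptor gene Adgrg1 6.49-fold (3.20 to 14.5). The heat shock genes Hspa1a and Hspa1b, which also respond to tissue digestion, were 4.73-fold (4.24 to 5.28) and 7.67-fold (5.77 to 10.4) higher. Il1a had a PBS to control ratio of 0.167 (0.0587 to 0.386), the desaturase gene Scd1 0.275 (0.136 to 0.513), the integrin gene Itgb5 0.268 (0.128 to 0.512) and the iron exporter gene Slc40a1 0.375 (0.285 to 0.487). Gpr155 and Frmd6 had ratios of 0.324 (0.187 to 0.534) and 0.356 (0.229 to 0.536). In T-like cells, 4 of 19 interferon-gamma members were higher and 1 was lower, and 5 of 23 type I members were higher and 0 lower, with medians of 0.46 and 0.63. The type I medians of fibroblast-like and epithelial-like cells were 0.20 and 0.22, at percentiles 100 and 98.4 of the random lists.

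In epithelial-like cells, the cornified envelope gene Sprr1a was 8.18-fold (7.62 to 8.80) higher in PBS and Pcp4 7.86-fold (6.95 to 8.90), and these genes led clusters 7 and 12. Thbs1 was 4.80-fold (4.13 to 5.59) higher. Higher in PBS as well were the histone gene Hist1h2ap 5.67-fold (4.57 to 7.07), Ube2c 4.30-fold (3.51 to 5.29), Mki67 3.33-fold (2.66 to 4.17) and Stmn1 3.59-fold (3.27 to 3.95). Of the cell cycle list, 8 of 10 members were higher, with a median log2 fold of 1.31, but within clusters 7 and 8 the medians were 0.565 and 0.757, both under 2-fold. Lactoferrin (Ltf) had a PBS to control ratio of 0.0649 (0.0429 to 0.0946), Dmbt1 0.117 (0.0954 to 0.142), Wfdc3 0.146 (0.116 to 0.183) and Gpx3 0.206 (0.196 to 0.217). The surfactant protein gene Sftpd, with 2 PBS UMIs, had a ratio of 0.0178 (0.00214 to 0.0651). The interferon-gamma list median was 0.02, with 0 of 19 members higher and 2 lower.

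The labels give no day for the PBS library, and how far a pair of libraries of the same condition would differ is not known here. The macrophage-like list median ranged from 0.42 to 0.99 with pseudocounts of 20 and 1 CPM.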

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

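These 3 values drew attention because a share of unnamed clusters, which the comparisons by gene leave out, or a neutrophil gene in a class that is not neutrophil-like, lay above its level in the control library. All were chosen after the data were seen. Cluster 12, an unnamed cluster with epithelial keratins, held 9.03% of PBS cells against 2.06% of control cells. Its cells held a median of 8995 UMIs, the highest of the 27 clusters, and expressed Krt18 at 2707, 2562 and 2478 CPM and Krt8 at 1921, 1930.2 and 2042 CPM in control, PBS and infected, with Areg at 1623, 2151 and 1365 CPM. Cluster 22, led by Ifitm1, Cd7 and Sct with dendritic and plasmacytoid dendritic markers, held 5.66% of infected cells against 0.168% of control cells. Its infected cells expressed Cxcl10 at 4876 CPM and Ccl5 at 3642 CPM.

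S100a9, a neutrophil gene, stood at 41.5 CPM in epithelial-like cells of the PBS library against 1.89 CPM in control. S100a8 there stood at 2.09, 61.0 and 42.6 CPM in control, PBS and infected. In fibroblast-like and T-like cells S100a8 stood at 5.47, 31.6 and 53.6 CPM, and 2.77, 34.98 and 26.9 CPM. The neutrophil-like class held 1, 6 and 97 cells.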

How the results depend on the processing

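The alternatives that named clusters without the leading genes, dropped clusters over 90% infected, counted shares among fibroblast-like and epithelial-like cells, or subtracted free RNA were added after seeing the data. No paired analysis was possible because each condition had 1 library, and for the same reason no library was left out. Each value was counted once per alternative setting, so these counts are of pairs of a value and a setting, and 1 value enters many times. Of pairs with a called main value, 1188 of 1193 for list medians kept their direction and 1055 stayed 2-fold. For gene folds, 5566 of 5593 such pairs kept it and 5333 stayed 2-fold, and for share ratios 160 of 166 and 150. The low-count filters do not act on single gene folds, so all 516 stayed the same under each. A change of pseudocount cannot turn the direction of a gene fold. Many of these genes were also named for large folds, so part of the kept directions was fixed by construction. Counting all pairs, 842 of 3519 for list medians, 1992 of 8772 for gene folds and 62 of 259 for share ratios moved beyond their intervals. Of pairs with a called main value, 5, 18 and 6 turned direction. Another 9 for gene folds, of Il5, Il13, Csf2 and Ccdc184 in T-like cells at resolution 2.0, came to 0. Of pairs with a main value under 2-fold, 165, 176 and 11 turned, among them those of the epithelial-like ratio of PBS over control.

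Shares are infected over PBS and folds are log2 of infected over PBS unless stated. Without clusters over 90% infected, the monocyte-like ratio was 1.58 and the fibroblast-like 0.720. The NK-like ratio turned to 2.34, the epithelial-like to 1.38 (1.14 over control) and the muscle-like ratio over control to 1.67. Interferon-gamma list medians were 1.49 in fibroblast-like and 1.33 in macrophage-like cells. In macrophage-like cells the resident list turned to 0.11 and 0.0748 over control, the antimicrobial list over control to -0.0179, Mrc1 to 0.15 and 0.0532, Hif1a to -0.13 and -0.0490, and Slc40a1 to 0.0881. In fibroblast-like cells Igfbp3 turned to 0.0341 and 0.14 over control, and Eln over control to 0.16. Removing cells changes the shares by construction, and fewer infected cells were left per class.

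Among fibroblast-like and epithelial-like cells alone, the epithelial-like ratio was 0.813 and the fibroblast-like turned to 1.06 (1.05 over control), since the monocytes left the denominator. Named without the leading genes, the fibroblast-like ratio was 0.305, the macrophage-like 0.330, the epithelial-like list median 3.83, and Il6 over control in macrophage-like cells turned to -0.10. With free RNA subtracted, the matrix list over control in epithelial-like cells turned from -1.44 to 0.68.

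With 500 genes the monocyte-like ratio was 15.9 and the epithelial-like list median 3.83. With 5% mitochondrial UMIs the fibroblast-like ratio was 0.419, the monocyte-like 14.6, the fibroblast-like list median 2.91, and Ifng in T-like cells turned to 0.35. Without doublet removal the fibroblast-like ratio was 0.336, the monocyte-like 14.5 and the T-like list median 2.33, while in T-like cells Ifng turned to 0.71 and Gzma (PBS over control) to -0.56. With Scrublet's threshold these were 16.0 for monocytes, 2.31 for the T-like list, 0.77 for Ifng and -0.54 for Gzma.

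At resolution 0.5 the fibroblast-like ratio was 0.307, the monocyte-like 111 and the epithelial-like list median 3.83. Its T-like class held 226, 301 and 356 cells, near the main T-like class joined with the NK-like class of 100, 121 and 94. In it Ifng turned to 3.73 and Gzma to -0.21, and to -0.00083 over control. The turn of Ifng there does not show a rise within T-like cells. At resolution 2.0 the epithelial-like ratio was 0.244, the macrophage-like 0.384, the monocyte-like 16.0 and Ifng in T-like cells 0.30. With response lists kept, the epithelial-like ratio was 0.354 and the monocyte-like 14.4.

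The remaining values are interferon-gamma list medians. TMM gave 2.58 in macrophage-like cells. Thinning gave 4.48 in epithelial-like and 2.65 in fibroblast-like cells. A pseudocount of 1 CPM gave 5.22, 3.10 and 2.56 in epithelial-like, fibroblast-like and macrophage-like cells, and 0.99 in macrophage-like PBS over control. A pseudocount of 20 CPM gave 3.07, 2.29, 1.79 and 0.42 for the same, and 1.52 in T-like cells. The filter of 5 UMIs gave 3.79 and 2.33 in epithelial-like and fibroblast-like cells, and turned the acute phase list of macrophage-like cells over control to -0.26. Pseudocounts act by construction on genes near 0. Elsewhere the cause was not tested.

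Of the 4 classes compared by gene, T-like cells were fewest, at 126, 180 and 259 cells. The B-like class held 18, 24 and 65, the muscle-like 46, 94 and 19, and the neutrophil-like 1, 6 and 97. A gene at 0 UMIs in a class was not detectable at that depth, which does not show that it was absent.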

Other observations

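The sources of several cytokine genes and of Nos2 were chosen for this paragraph after their values were seen. Il27, a cytokine of myeloid cells, stood at 0.353, 0.730 and 81.1 CPM over all cells of control, PBS and infected, and monocyte-like cells held 86.2% of its infected UMIs. Nos2 had 0 UMIs in control and PBS and stood at 39.7 CPM in infected, 76.7% of it in monocyte-like cells. Il33, an alarm cytokine of stroma, stood at 107, 98.7 and 236 CPM in fibroblast-like cells, which held 90.9% of the infected UMIs. The granulocyte growth factor gene Csf3 stood at 0.405, 0.0960 and 55.0 CPM there and at 62.1 CPM in infected cluster 12. Cxcl13, which draws B cells, stood at 126, 153 and 237 CPM in fibroblast-like cells.

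Unnamed clusters had part of these programs. Cluster 9, led by Retnla, Ear2 and Cd209a, held 58.1% and 46.1% of Il1b UMIs in control and PBS, and expressed Il12b at 15.2, 26.3 and 2.70 CPM. Cluster 12 expressed Cxcl1 at 129, 254 and 279 CPM. Ccl5 came from NK-like cells in control, 60.9% of its UMIs, and from monocyte-like cells in infected, 79.2%. Il1b reached its highest infected level in neutrophil-like cells, 7969.9 CPM.

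Of the tests below, the 3 on Saa3 were chosen only after the result was seen. Saa3 in infected fibroblast-like cells differed between clusters, with a high mean in cluster 23 and a level near background in the shared clusters. Cluster 23 was not uniform. In the random thinning that the figure shows, 387 of its 845 cells had 0 Saa3 UMIs at 1000 UMIs per cell and 157 had 21 or more. Shared barcodes, too few UMIs and doublets with monocytes were each tested as a technical cause. The first 2 were argued against: 2.31% of shared-cluster cells had a barcode of another library, and the thinned share with Saa3 was still 6.89 times higher in cluster 23. Lyz2 in cluster 23 was 4.84% of its monocyte-like level, where 25% was needed. A mean over the cluster cannot exclude doublets in part of it, and its median Scrublet score was 0.076 against 0.0547 in the shared clusters. Saa3 stood at 302 CPM in infected monocyte-like cells and 10895 CPM in cluster 23, which argues against monocytes as its source. A candidate biological explanation is a response of part of the fibroblasts, for example those near the route of the bacteria, but no position was measured and library and infection cannot be separated.

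The cell cycle list was higher in epithelial-like cells of PBS than of control, at a median log2 fold of 1.31. Another mix of epithelial-like clusters could not be ruled out, since the medians within clusters 7 and 8 were 0.565 and 0.757, below the class value, and the lower one missed the limit of 0.75 set beforehand. Within these clusters 9 of 10 and 10 of 10 members were still above 0 in PBS over control, which a change in the mix of the 2 clusters alone does not predict. A different mix of cycling and other cells inside a cluster could give the same signs. Random lists matched to the class were also above 0, at a median of 0.099. Mki67 stood at 3.12 and 3.54 CPM in control and PBS cluster 7, and at 65.3 and 125 CPM in cluster 8. RNA of cluster 12 also stayed open: the share needed, 47.2%, was 1.49 times the share its leading genes allowed, 31.7%, short of the 2 times set as the limit. A response to the injection, or mice at another stage of their cycle, may also be the source and was not tested.

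The interferon-gamma list was higher in infected fibroblast-like, epithelial-like and T-like cells, where RNA from the many monocyte-like cells might carry it. The tables argue against this, because the share of monocyte-like RNA the members needed was 73.6%, 61.7% and 22.3%, or 16.8, 21.9 and 2.98 times the share that 5 abundant monocyte genes allowed. Expression in the cells themselves, in line with Ifng in NK-like cells, remains as a hypothesis. Macrophage-like cells were not tested, since they share those genes with monocytes.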
